A study of Danio rerio with 3 samples.

How the data were processed

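Single-cell RNA was measured in 3 libraries of wild-type adult zebrafish aged 4 months: 1 control library, 1 library from 1 day after spinal cord injury and 1 library from 7 days after it. The deposited files hold raw unique molecular identifier (UMI) counts per gene and cell barcode, with no normalisation. Cell Ranger 5.0.0 made the matrices, per the file headers, and GRCz11 is the genome build named in the submitters' processing notes. The libraries were made with a droplet-based single-cell 3' kit, version V3, per the labels' protocols. The gene annotation release, and whether intronic reads were counted, are not given in the sources used here. No barcode had fewer than 500 UMIs in the deposited counts. The files hold 27771 gene entries with 27062 distinct symbols; counts of entries that share a symbol (550 symbols) were added up.

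Cells were kept with at least 500 UMIs, 300 genes and at most 20% mitochondrial UMIs. The gene minimum removed 4, 21 and 3 barcodes in the control, day 1 and day 7 libraries and the mitochondrial maximum removed 7, 45 and 27 (a barcode may fail both), which left 12556, 14127 and 14569. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold called 0, 3 and 0 doublets, so a fixed score of 0.12 was used, chosen after the scores had been seen. It called 1296, 1228 and 1224 doublets (10.3%, 8.69% and 8.40%) and left 11260, 12899 and 13345 cells, the cells counted in every share unless stated.

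Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were standardised, with values limited to 10, and reduced to 30 principal components with all libraries together and no batch correction. Clusters came from a shared-neighbour graph (20 neighbours) and the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, seed 1). Each cluster took the name of the type, out of 17 with markers fixed beforehand, whose markers had the highest mean log2 fold over the median of the other clusters. A name required a score of at least 0.5, with 5 CPM added to each level, and at least 3 markers that were 2-fold higher and had a UMI in 5% of cells. A cluster stayed unnamed when its 10 leading genes, among genes with a UMI in at least 25% of its cells, held more markers of another type. This leading-gene check was tried in 5 versions after the clusters had been seen, and the version used was chosen then. Names are written as "X-like", since they rest on markers alone. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0, and figures used matplotlib 3.10.9.

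With 1 library per group no test, p-value or standard error between groups can be given, and cells are not replicates. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. Gene levels are UMIs summed over the cells of a class in a library, as CPM of that sum, with exact Poisson intervals; ratios of 2 libraries carry exact conditional binomial 95% intervals. All intervals cover counting error only, not differences between animals, dissections or library preparations. Intervals of gene levels and ratios treat UMIs as independent, so they are too narrow where a gene's UMIs are gathered in few cells. A count of 0 allows up to 3 counts, and a ratio against 0 is given as a lower bound with that floor over the class sum.

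Before the data were examined, 20 gene lists, the marker lists, the rule for named genes and most alternatives were fixed. For a list, the median log2 ratio was taken over members with at least 10 UMIs in the 2 class sums together, with 0.5 added to each count, a pseudocount that had not been fixed beforehand. Intervals of medians are order-statistic 95% intervals over members, which are not replicates. The percentile is that of the median among 10000 random lists of equal size drawn from 20 expression bins. Medians were also computed with members at 0 in 1 library set to the floor.

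Gene levels were compared in the 4 named classes with the largest smallest-library cell number. A gene could be named when, in the library where it was higher, it had at least 100 UMIs in the class, a UMI in at least 10% of the cells and a class CPM of at least 0.5 times its CPM over all kept cells, and when its ratio interval lay wholly beyond a 2-fold difference. Mitochondrial, ribosomal protein and haemoglobin genes and genes named only by a clone or locus code were left out. Genes were ranked by the interval bound nearest to no difference. The 4 highest and 3 lowest were named for each time against control, and the 2 highest and 2 lowest for day 7 against day 1. List examples are the members with the largest and smallest ratio and at least 100 UMIs; which lists get examples was decided after the list medians had been seen. Beyond the rule, lin28a and c6 in oligodendrocyte precursor-like cells at day 7 and the marker genes of unnamed clusters were chosen after their values were seen. Some genes that the rule or the list examples select are not reported here.

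Cycling cells had UMIs of at least 2 cell cycle genes after each cell was thinned to 1000 UMIs, with shallower cells left out. Free RNA, which droplets share, was gauged for each named gene by its CPM in T or NK lymphocyte-like and in erythrocyte-like cells of the same library. A gene is said to be above both gauges when its class CPM is over 2 times each of them. The level is taken in the library where the gene is higher. A gene that lymphocyte-like or erythrocyte-like cells express themselves can fall short of a gauge for that reason, so that a gene not above both gauges is not shown to be free RNA. The gauge cells are also shallow. At day 1 the median was 669.5 UMIs in erythrocyte-like and 756.5 in lymphocyte-like cells, against 1601 in neuron-like cells. The same number of free UMIs per droplet is a higher CPM in shallower cells, so the gauges can be too strict. These gauges, the list values in lymphocyte-like cells and the values in cluster 13 were added after the data had been seen.

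The interval, the naming threshold and the list medians were tested on simulated counts made from the oligodendrocyte-like class sums. Of 18166 genes, 96.2% had an interval that held the true ratio. The counts were drawn from the Poisson model that the intervals assume, so this checks the computation only. It does not cover UMIs gathered in few cells, as for crlf1a in oligodendrocyte-like cells at day 1 (2803 UMIs in 14.1% of cells). Of 50 genes set 4-fold higher, 100% had an interval beyond a 2-fold difference, and of 50 set to 0.25 of their level, 98% did. Genes set at 1.5-fold or 0.667 gave 0%, and 1 of 17966 unchanged genes did. A list of 25 genes set 4-fold higher had a median log2 ratio of 1.96 (percentile 100), and a list of 25 unchanged genes −0.02 (percentile 37.4).

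Alternatives fixed beforehand were doublet calls kept in with new clustering, a stricter filter (1000 UMIs and 10% mitochondrial UMIs), Leiden resolution 2.0, expression centred within each library, each library clustered alone, median-of-ratios scaling, the mean of per-cell CPM, thinning to 1000 UMIs, subtraction of free RNA estimated from haemoglobin, list members with at least 50 UMIs, and cycling cells with at least 3 genes or after thinning to 2000 UMIs. Added after seeing the data were the other versions of the leading-gene check, shares without cluster 1, free RNA subtraction at 5%, cycling shares without cluster 15, and free RNA gauges without the erythrocyte-like cluster 31. After either subtraction of free RNA, a count under 3 was set to 3. Ratios of genes whose control count was set to this floor reflect the floor and are no estimate without free RNA. Among them are lin28a, clcf1, entpd2b, gab2 and fap.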

Results

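Single-cell transcriptomes of the spinal cord of wild-type adult zebrafish, aged 4 months, were collected from a control group, at 1 day after spinal cord injury and at 7 days after injury. Each group had 1 library, so there were no replicates and differences between groups could not be tested. The control library held 12566 barcodes and 25525746 UMIs, the day 1 library 14173 barcodes and 27431982 UMIs, and the day 7 library 14596 barcodes and 30485246 UMIs. Median UMIs per barcode were 1485, 1370 and 1432, and the median share of mitochondrial UMIs was 0.362%, 0.455% and 0.723%. After filters and removal of doublet calls 11260, 12899 and 13345 cells remained. Values in a series of 3 are in the order control, day 1, day 7, and brackets hold 95% intervals that cover counting error only.

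The first comparison asked which cell types made up the cord at each time. Oligodendrocyte-like cells were the largest class in the control library and made up smaller shares after injury: 37.5% [36.6 to 38.4], 29.2% [28.4 to 30] and 19.9% [19.2 to 20.6] of cells. The day 7 share leaves out the unnamed cluster 1 (3458 day 7 cells), whose highest marker score was narrowly for oligodendrocytes. With that cluster it would lie above control, so the lower share at day 7 depends on the naming. Neuron-like cells made up 23.6% [22.8 to 24.3], 28.2% [27.4 to 28.9] and 11.6% [11 to 12]. Ependymo-radial glia-like cells, the cells that line the central canal and act as progenitors in the fish cord, made up a larger share at each time after injury: 10.9% [10 to 12], 13.2% [12.7 to 13.8] and 15.4% [14.8 to 16.0]. Microglia or macrophage-like cells made up 3.22% [2.91 to 3.57] in control, 1.19% [1.01 to 1.40] at day 1 and 6.95% [6.52 to 7.39] at day 7.

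Oligodendrocyte precursor-like cells made up 8.99%, 9.71% and 4.47%, and neurons that contact the cerebrospinal fluid 5.57%, 5.28% and 2.46%. Cluster 26 held 210, 95 and 10 of the latter cells, at a median of 732.5 UMIs in control. A version of the leading-gene check that left cluster 26 unnamed gave them 3.70% in control and 4.54% at day 1. At Leiden resolution 2.0 they made up 3.81% in control and 4.75% at day 1. Their order at these times therefore depends on the clustering and on the name of cluster 26. T or NK lymphocyte-like cells made up 6.49%, 3.86% and 3.93%, B lymphocyte-like cells 0.782%, 0.744% and 0.952%, and erythrocyte-like cells 1.26%, 2.23% and 1.78%. With the stricter cell filter erythrocyte-like cells made up 0.334%, 0.825% and 0.25%, so that day 7 was below control. Endothelial-like cells (0.968%, 0.961% and 1.55%) and fibroblast-like cells (0.471%, 0.814% and 1.05%) made up their largest shares at day 7. With each library clustered alone, endothelial-like cells made up 1.74% and fibroblast-like cells 0% at day 1. Schwann cell-like cells were a single cluster with 0 of 11260 control cells, which allows a share of up to 0.0266%, then 6 cells at day 1 and 535 at day 7 (4.01% [3.68 to 4.36]).

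Some classes were held by different clusters in different libraries. The oligodendrocyte-like class consisted mainly of cluster 0 in control (4043 of its 4217 cells), cluster 2 at day 1 (3335 of 3761) and cluster 3 at day 7 (2532 of 2653). In the microglia or macrophage-like class, cluster 13 held 178, 17 and 868 cells and cluster 24 held 185, 137 and 59. Cluster 24 scored 1.926 for microglia or macrophages and 1.3 for CSF-contacting neurons. Its 7 raised markers did not include csf1ra, csf1rb, apoeb or p2ry12, which were raised in cluster 13. Among ependymo-radial glia-like cells, cluster 4 held 476, 489 and 1072 cells, cluster 9 held 405, 707 and 313, and cluster 15, whose leading genes include the cell cycle gene top2a, held 140, 200 and 479. In the oligodendrocyte precursor-like class, cluster 7 held 627, 657 and 281 cells, cluster 11 held 350, 557 and 269, and cluster 30 held 35, 38 and 46. Cluster 11 scored 1.243 for precursors and 0.883 for Schwann cells, with 4 precursor markers. A cluster that comes almost wholly from 1 library may reflect that library.

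2 unnamed clusters were large in a single library, and the thresholds that left them unnamed were set after the clusters had been seen. Cluster 1 held 0.284%, 0.799% and 25.9% of cells. Its leading genes combined microglial apoeb, apoc1 and lgals3bpb with glial fabp7a and gfap. The highest marker score of cluster 1 was for oligodendrocytes (1.737, with 11 markers, against 1.724 for microglia or macrophages). Named by that score alone, it would put the day 7 share of oligodendrocyte-like cells above control. Cluster 20 held 0.0266%, 3.81% and 0.0674%, with il1b, spi1b and csf1ra, genes of myeloid immune cells, among its leading genes. Its highest marker score was for neutrophils (3.825, with mpx and lect2l among 8 markers, against 2.746 for microglia or macrophages), and 3 of 5 versions of the leading-gene check named it neutrophil. Without cluster 1 the day 7 shares were 26.8% for oligodendrocyte-like, 15.6% for neuron-like, 20.8% for ependymo-radial glia-like and 9.38% for microglia or macrophage-like cells. Other clusterings named similar cells. Leiden resolution 2.0 placed a cluster of 25, 84 and 3352 cells in the ependymo-radial glia-like class, whose day 7 share became 40.6%. With doublet calls kept in, microglia or macrophage-like cells made up 3.72%, 6.58% and 31.3%, and with expression centred within each library 5.36%, 7.07% and 31.1%, so that the day 1 share was above control in both. In 2 versions of the leading-gene check cluster 2 stayed unnamed, which left 3.30% oligodendrocyte-like cells at day 1. The stricter cell filter gave lymphocyte-like (T or NK) shares of 3.41%, 1.43% and 2.23%.

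**Figure D1:**
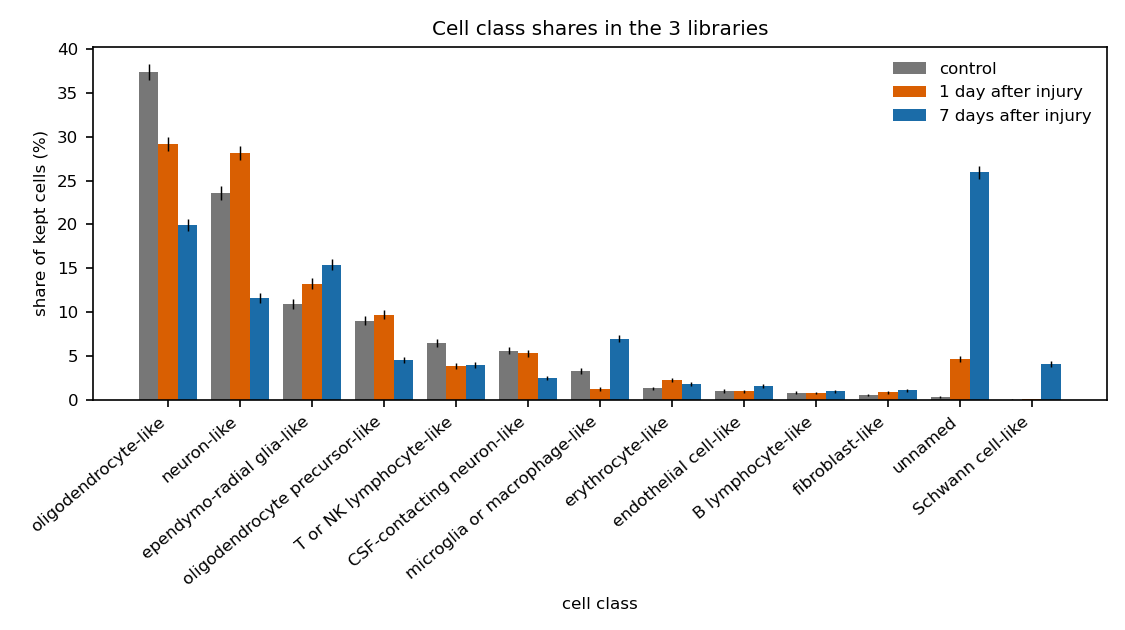
Share of kept cells (%, vertical axis) in each named class and in unnamed clusters for the control, day 1 and day 7 libraries, 1 library each; bars are shares and error bars are exact 95% binomial intervals of counting error. Oligodendrocyte-like cells are highest in control (37.5%) and unnamed cells highest at day 7 (26.0%).

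Day 1 after injury was compared with control to ask what each cell type expresses soon after injury. Genes of the interferon response and of glial injury and reprogramming were higher at day 1 in all 4 classes measured. Oligodendrocyte precursor-like and ependymo-radial glia-like cells had high levels of lin28a, an RNA-binding protein of reprogramming and regenerating cells, which was almost undetected in control. In the precursor-like cells crlf1a and clcf1, which encode the 2 parts of a secreted cytokine that signals through the ciliary neurotrophic factor receptor, were higher together with the receptor tyrosine kinase gene met. Cholesterol synthesis genes were lower in ependymo-radial glia-like cells, where 22 of 23 measured members had a lower level.

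In oligodendrocyte precursor-like cells, lin28a (ENSDARG00000016999) was at 598 CPM at day 1 (1611 UMIs) with 0 UMIs in control, at least 501-fold higher. A lin28a UMI was found in 12.5% of these cells (median 1998 UMIs per cell) and in 0.602% of lymphocyte-like cells (median 756.5), which should lack it. crlf1a (ENSDARG00000024365) was at 855 CPM against 1.59, 537-fold higher [210 to 1974]. clcf1 (ENSDARG00000076140) was at 194 CPM against 0.398 from 1 UMI, 489-fold higher [87.3 to 19338]. met (ENSDARG00000070903) was at 275 CPM against 2.78, 98.7-fold higher [47.7 to 246]. All 4 were above both free RNA gauges. Within the day 1 library lin28a (1171 CPM), crlf1a (1877 CPM) and clcf1 (423 CPM) were highest in cluster 11, so their class levels come largely from that cluster. met was highest in the ependymo-radial glia-like clusters 25 (663 CPM) and 9 (654 CPM), above its precursor-like level, so it was not particular to precursor-like cells. With free RNA subtracted at 5% clcf1 was 161-fold higher, a value set by raising its control count to the floor of 3. After thinning crlf1a was 354-fold higher. The haemoglobin estimate gave 208-fold for lin28a, 268-fold for crlf1a and 66.0-fold for clcf1, each with the control count at that floor. The lowest genes were the potassium channel gene kcnt2 (10-fold lower [6.76 to 15.3]), cntd2 (7.97-fold) and vstm4a (5.59-fold).

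Ependymo-radial glia-like cells had lin28a at 254 CPM against 0.396 in control, from 1 UMI (642-fold [115 to 25365]; 208-fold with free RNA subtracted at 5%, 70.29-fold with the haemoglobin estimate and 235-fold after thinning). c7a, which encodes a component of the complement membrane attack complex, was at 599 CPM against 17.0 (35-fold [26.1 to 48.8]). slc16a9a, a transporter gene, was 56.2-fold higher [25.7 to 154], or 28.4-fold after thinning. timp2b, an inhibitor of matrix metalloproteinases, was 49.5-fold higher, but its 176 CPM was matched by 157 in lymphocyte-like and 178 in erythrocyte-like cells. Lower genes were the fatty acid desaturase gene fads2 (7.52-fold), dicp1.1 (7.06-fold; not above both gauges) and ahdc1 (6.81-fold).

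In oligodendrocyte-like cells the most increased gene was crlf1a, at 525 CPM against 3.10 (170-fold [112 to 271]; 93.8-fold for the mean of per-cell CPM). The metalloproteinase gene adam8b (75.1-fold), c7a (66.0-fold) and the interferon-induced GTPase gene gbp1 (62.7-fold) were not above both gauges; without cluster 31 among the erythrocyte-like cells gbp1 was. dicp1.1 (8.41-fold), fbxo32 (6.06-fold) and auts2b (5.91-fold) were lower. In neuron-like cells none of the 4 highest genes was above both gauges: the stress-induced transcription factor gene atf3 was at 169 CPM against 5.19 (32.5-fold [22.8 to 48.1]) with 109 CPM in lymphocyte-like and 297 CPM in erythrocyte-like cells, and igfbp1a was 26.9-fold (15.6-fold for the mean of per-cell CPM), adam8b 25.1-fold (46.1-fold after thinning) and timp2b 19.1-fold higher. Both gauge classes are shallower than neuron-like cells, so this does not show that these genes are free RNA. Only 2 genes qualified as lower, tbc1d19 (2.34-fold) and loxl3b (2.28-fold); loxl3b was at 139 CPM in control, against 89.6 CPM in erythrocyte-like and 1930 CPM in lymphocyte-like cells.

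**Figure D2:**
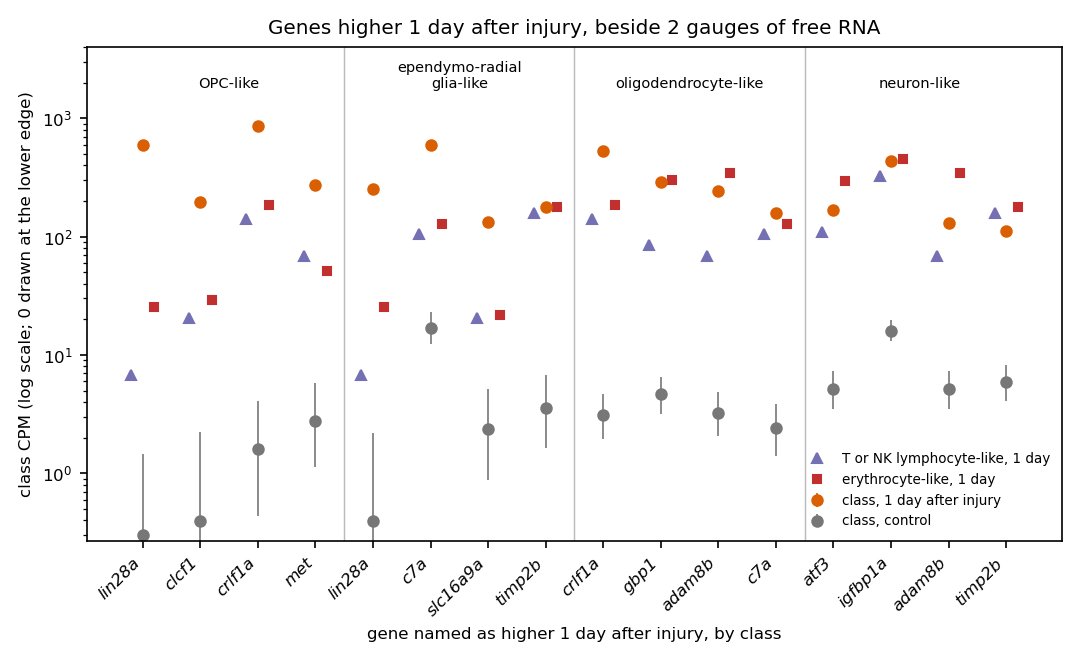
Class CPM on a log axis for the named genes that were higher at day 1 than in control, by class, with points for the control and day 1 libraries and for the lymphocyte-like and erythrocyte-like cells of the day 1 library; error bars are exact Poisson 95% intervals. All 4 genes of the oligodendrocyte precursor-like class, and none of the neuron-like class, are over 2 times both gauges.

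Interferon response genes had a median log2 ratio of 2.53 [1.55 to 4.21] in oligodendrocyte-like cells at day 1, with 18 of 18 measured members higher, from gbp1 to rsad2 (1.23-fold [1.09 to 1.38]; not above both gauges). The medians were 2.51 [0.53 to 3.21] in precursor-like (16 of 16 higher), 2.25 [0.79 to 3.25] in neuron-like (15 of 16) and 0.65 [0.35 to 1.6] in ependymo-radial glia-like cells (13 of 16). In lymphocyte-like cells it was 0.33. Examples were stat1b (8.70-fold) and stat1a (1.33-fold) in precursor-like and irf1b (9.73-fold) in neuron-like cells, all 3 below the erythrocyte-like level (irf1b at 29.3 CPM, against 138 CPM). Lymphocyte-like cells have irf1b of their own, at 205 CPM in control against 22.4 CPM over all cells, and are no gauge for it. In control their stat1b (80.9 against 18.8 CPM) and stat1a (324 against 158 CPM) were above the level over all cells too, while rsad2 (39.1 against 40.5 CPM) was not. The lymphocyte-like median of this list is therefore no clean gauge of free RNA at either time. The glial injury and reprogramming list had medians of 1.71 in oligodendrocyte-like (33 of 36 higher), 1.09 in neuron-like (30 of 36), 1.02 in precursor-like (27 of 35) and 0.78 in ependymo-radial glia-like cells (26 of 36), against 0.70 in lymphocyte-like cells. In ependymo-radial glia-like cells fgfr2, a fibroblast growth factor receptor gene of this list, was 2.59-fold lower [2.36 to 2.85].

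Immediate-early and dissociation stress genes were higher too, with medians of 1.49 in oligodendrocyte-like (24 of 27), 1.39 in precursor-like (23 of 26), 0.57 in neuron-like (21 of 28) and 0.42 in ependymo-radial glia-like cells (20 of 27), and 0.48 in lymphocyte-like cells. This list responds to tissue handling as well as to injury. Cytokine and chemokine genes had medians of 1.45, 0.51, 0.96 and 1.46 in oligodendrocyte-like, neuron-like, ependymo-radial glia-like and precursor-like cells, against 0.22 in lymphocyte-like cells; cxcl18b was 20.5-fold higher in oligodendrocyte-like cells, but its 40.5 CPM was below both gauges, and cxcl12a was 2.15-fold lower. Antigen presentation genes had medians of 1.26, 0.81, 0.33 and 1.29 in the same order and −0.21 in lymphocyte-like cells, with psme1 8.33-fold higher and cd74a 1.76-fold lower in oligodendrocyte-like cells. These 2 and cxcl12a were not above both gauges either. Lymphocyte-like cells have cd74a of their own (600 CPM in control against 220 CPM over all cells), so their median is no clean gauge for this list. Complement genes had a median of 1.91 in precursor-like cells (8 of 9 higher), against 1.44 in lymphocyte-like cells. There c6 was 3.76-fold higher [3.23 to 4.39] (1.88-fold with the haemoglobin estimate), at 312 CPM against 39 in lymphocyte-like and 228 in erythrocyte-like cells, while c7b, at 1956 CPM, was below its 2223 CPM in lymphocyte-like cells.

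Among the lists that were lower at day 1 in some classes were those of cholesterol synthesis, myelin, synapses and the Notch pathway. Cholesterol synthesis genes had a median of −0.93 [−1.24 to −0.60] (percentile 0) in ependymo-radial glia-like cells. It was −0.33 in oligodendrocyte-like cells (18 of 23 lower; insig1 2.34-fold) and −0.47 in lymphocyte-like cells. Myelin genes had a median of −0.36 in oligodendrocyte-like cells (13 of 19 lower), where aspa was 2.47-fold lower and the oligodendrocyte transcription factor gene sox10 was 1.40-fold higher. It was −0.61, −1.06, −0.78 and −0.74 in neuron-like, ependymo-radial glia-like, precursor-like and lymphocyte-like cells, which are not expected to make myelin proteins. Synapse genes were lower in neuron-like cells for 32 of 36 members, with a median of −0.25 [−0.39 to −0.18] and the glycine transporter gene slc6a5 1.74-fold lower; the medians were −0.14, −0.54, −0.32 and −0.13 in oligodendrocyte-like, ependymo-radial glia-like, precursor-like and lymphocyte-like cells. Notch pathway genes were lower in ependymo-radial glia-like cells for 15 of 21 members (median −0.42 [−0.60 to 0.02]), with the ligand gene jag2b 3.30-fold higher and the target gene her6 1.97-fold lower. Of these examples aspa and jag2b were not above both gauges.

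Because the oligodendrocyte-like class is a different cluster in each library, its gene differences are also differences between clusters. Subtracting free RNA at the share estimated from haemoglobin, 80.6%, 59.8% and 87.1% of UMIs, moved 85 of 134 named ratios beyond their intervals and turned 8, among them rsad2, cd74a and sox10 in oligodendrocyte-like and loxl3b in neuron-like cells at day 1. That share is the haemoglobin percentage outside erythrocyte-like cells (0.0696% in control) over that of all kept cells (0.0863%). Nearly the same cells enter both, and no profile of free RNA was measured. It is therefore no measurement of free RNA, and a ratio that it turns is not shown to be due to free RNA. With only members of at least 50 UMIs, day 1 medians were 2.33 for cytokines in neuron-like, 2.67 for complement and 0.51 for antigen presentation in precursor-like cells. After thinning, the cytokine gene cxcl18b in oligodendrocyte-like cells was 13.4-fold higher.

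**Figure D3:**
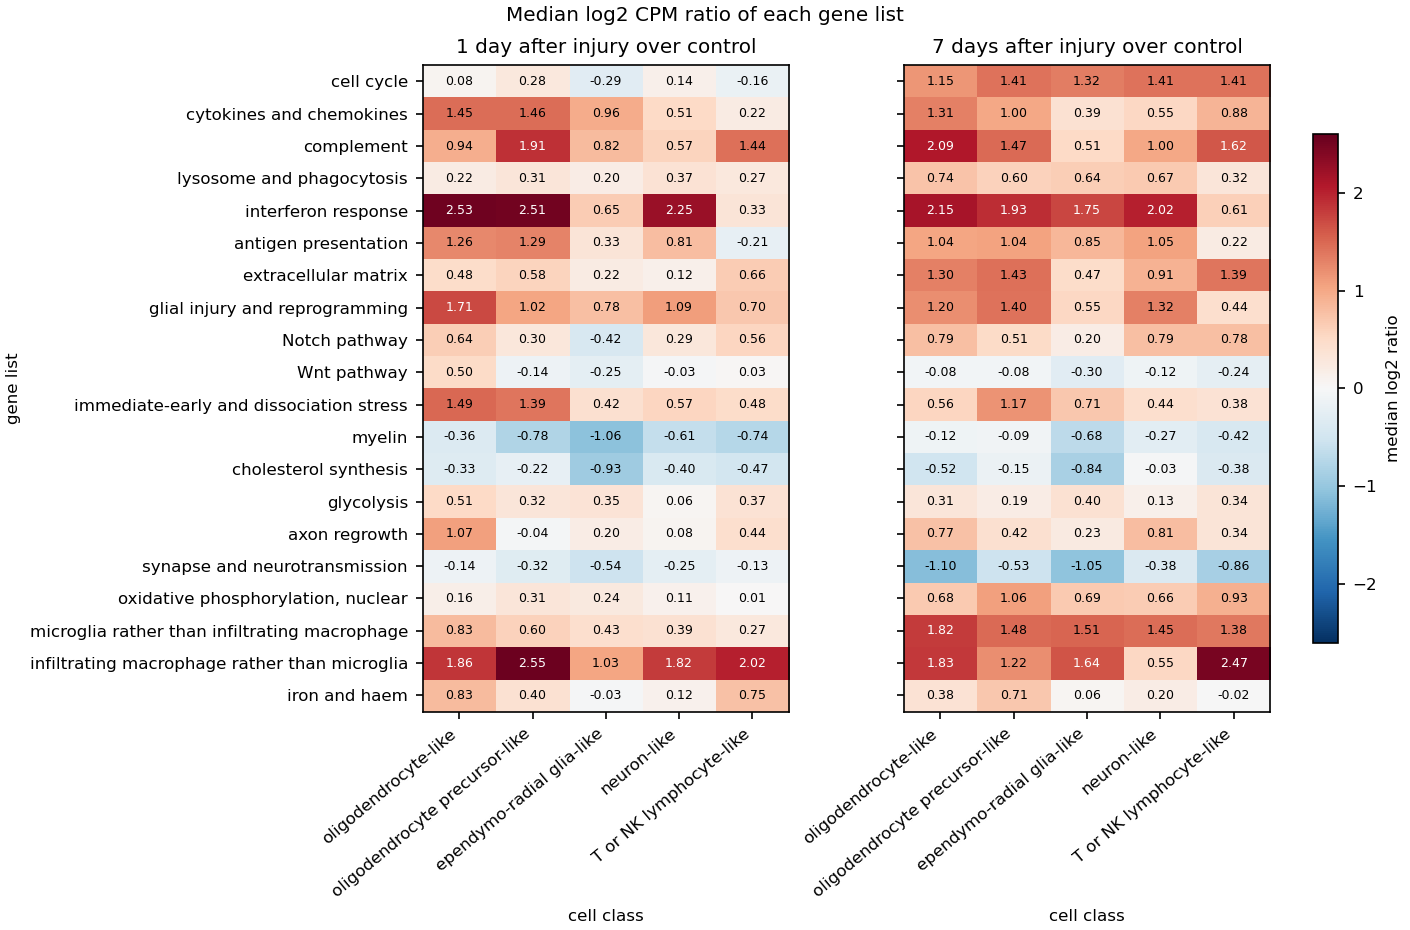
Median log2 ratio of list members (colour and number) for each gene list and class, for day 1 and day 7 against control, 1 library per group. Lymphocyte-like cells are shown as a gauge of free RNA, though they express members of some lists themselves, and no error is drawn. Interferon response genes are higher in every class at both times, and cell cycle genes are highest at day 7 (1.15 to 1.41).

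Day 7 after injury was compared with control to ask which differences are found during the later response. Cell cycle genes were higher at day 7 in all 4 classes and in lymphocyte-like cells, and the share of cycling ependymo-radial glia-like cells was 21.4% against 8.07% in control. Interferon response and glial injury genes were again higher in the 4 classes, extracellular matrix and oxidative phosphorylation genes were higher, and synapse genes were lower. In ependymo-radial glia-like cells cholesterol synthesis genes were lower for 22 of 23 members, as at day 1, and lin28a was at 150 CPM.

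After thinning to 1000 UMIs, cycling cells made up 8.07% [6.35 to 10.1], 6.78% [5.43 to 8.34] and 21.4% [19.5 to 23.4] of ependymo-radial glia-like cells (unthinned 12.7%, 12.8% and 37.1%; median 1332, 1414 and 1867 UMIs). In precursor-like cells the shares were 4.29% [3.09 to 5.77], 5.15% [3.93 to 6.61] and 12.7% [10 to 16] (unthinned 10.2%, 10.7% and 25.2%; median 2356.5, 1998 and 2265.5 UMIs). Neuron-like cells, which do not divide and so show the background, had 0.532% [0.266 to 0.951], 0.795% [0.499 to 1.2] and 5.03% [3.92 to 6.35] (unthinned 2.41%, 2.48% and 14.4%; median 1810.5, 1601 and 1812 UMIs). Oligodendrocyte-like cells had 1.49% [1.098 to 1.98], 1.6% [1.12 to 2.21] and 4.55% [3.75 to 5.45] (unthinned 3.82%, 2.90% and 16.4%), above that background in control, with intervals that overlap it at day 1 and day 7. Lymphocyte-like cells, which can divide, had 10.9%, 12.8% and 30.1% of 275, 125 and 196 cells. Thinning left out 364, 497 and 304 ependymo-radial glia-like and 56, 126 and 45 precursor-like cells. With at least 3 cell cycle genes the ependymo-radial glia-like shares were 5.65%, 4.05% and 10.7%, and after thinning to 2000 UMIs they were 12.1%, 10.1% and 32.1%. Cluster 15 held 45 of 70, 50 of 82 and 203 of 375 cycling cells of this class, with shares of 43.7% [33.9 to 53.8], 38.8% [30.3 to 47.7] and 51.9% [46.8 to 57.0] of its cells; without it the class had 3.27% [2.13 to 4.79], 2.96% [2.03 to 4.15] and 12.6% [10.9 to 14.5].

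**Figure D4:**
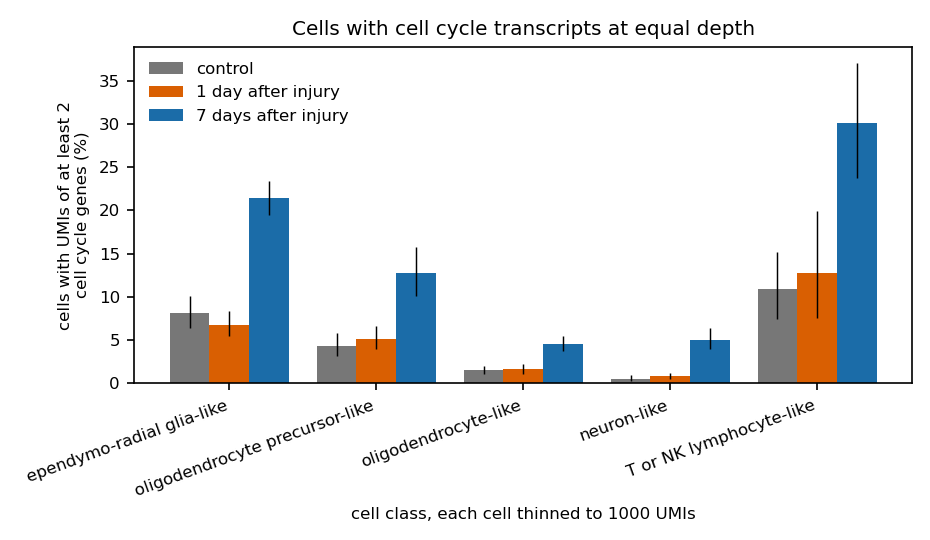
Share of cells (%, vertical axis) with UMIs of at least 2 cell cycle genes after thinning to 1000 UMIs, by class and library; bars are shares and error bars exact 95% binomial intervals of counting error. Day 7 is highest in each class, and neuron-like cells, the background, reach 5.03%.

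The cell cycle list had day 7 medians of 1.32 [0.98 to 1.65] in ependymo-radial glia-like (27 of 27 higher), 1.41 [0.96 to 1.79] in precursor-like (24 of 27), 1.41 in neuron-like (26 of 26), 1.15 in oligodendrocyte-like (24 of 27) and 1.41 in lymphocyte-like cells. In ependymo-radial glia-like cells cdk1, the kinase that starts mitosis, had 121 UMIs at day 7 and 0 in control, at least 16.4-fold higher, and the replication licensing gene mcm2 was 1.35-fold higher [1.03 to 1.78]. In precursor-like cells top2a was 3.80-fold higher [2.75 to 5.31]. None of these 3 was above both gauges. Lymphocyte-like cells, of which 30.1% were cycling at day 7, are no clean gauge of free RNA for cell cycle genes. All 3 fell short of the erythrocyte-like gauge, which rested on 2, 5 and 9 UMIs for cdk1, mcm2 and top2a. Interferon response medians were 2.15 [0.69 to 2.47] in oligodendrocyte-like (17 of 18 higher), 2.02 in neuron-like (16 of 17), 1.93 in precursor-like (13 of 14) and 1.75 in ependymo-radial glia-like cells (17 of 19), against 0.61 in lymphocyte-like cells. With only members of at least 50 UMIs the oligodendrocyte-like median was 1.31; after thinning it was 1.55 and the ependymo-radial glia-like median 0.97. ifi45 was 12.3-fold higher in neuron-like and 10.5-fold in precursor-like cells, where its CPM was below the lymphocyte-like level of 197. Glial injury medians were 1.40 in precursor-like (25 of 34), 1.32 in neuron-like (32 of 37), 1.2 in oligodendrocyte-like (31 of 37) and 0.55 in ependymo-radial glia-like cells (24 of 36), against 0.44 in lymphocyte-like cells.

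Extracellular matrix genes had medians of 1.43 in precursor-like (30 of 34 higher), 1.30 in oligodendrocyte-like (33 of 35), 0.91 in neuron-like and 0.47 in ependymo-radial glia-like cells, but 1.39 in lymphocyte-like cells. In ependymo-radial glia-like cells the gelatinase gene mmp9 was 33.7-fold higher [21.0 to 58.1] (17.2-fold after thinning) and the thrombospondin gene thbs1b 3.69-fold lower [3.45 to 3.96]. Nuclear genes of oxidative phosphorylation had medians of 0.68, 0.66, 0.69 and 1.06 in oligodendrocyte-like, neuron-like, ependymo-radial glia-like and precursor-like cells, and 0.93 in lymphocyte-like cells. The share of ribosomal protein UMIs over all kept cells differed too, at 0.920%, 1.51% and 2.82%, so a difference in RNA composition between libraries is open here. Axon regrowth genes were higher in neuron-like cells for 24 of 30 members, with a median of 0.81 [0.52 to 1.02] against 0.08 at day 1 and 0.34 in lymphocyte-like cells at day 7; atf3 was 13-fold higher [8.94 to 19.6] (6.21-fold after thinning; not above both gauges) and the neuropeptide gene galn 1.54-fold lower (1.05 times control with the haemoglobin estimate). Synapse genes were lower in neuron-like cells for 32 of 36 members (median −0.38 [−0.50 to −0.17]), with the synapsin gene syn2b 1.71-fold lower [1.55 to 1.90] (level with control with the haemoglobin estimate); the medians were −1.10, −1.05, −0.53 and −0.86 in oligodendrocyte-like, ependymo-radial glia-like, precursor-like and lymphocyte-like cells. Myelin genes had a median of −0.12 in oligodendrocyte-like cells, where mbpb was 1.89-fold higher [1.82 to 1.96] (not above both gauges) and nfasca 3.01-fold lower [2.94 to 3.08]. The cholesterol synthesis median was −0.84 [−1.09 to −0.51] (percentile 0) in ependymo-radial glia-like, −0.52 in oligodendrocyte-like and −0.38 in lymphocyte-like cells.

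Among named genes, precursor-like cells had the ectonucleotidase gene entpd2b (ENSDARG00000044795) at 120 CPM against 0.796 from 2 UMIs (151-fold [41.3 to 1260]; 99.5-fold with free RNA subtracted at 5%). dysf (ENSDARG00000007370), which encodes the membrane repair protein dysferlin, was at 454 CPM against 7.96 (57.0-fold [36.6 to 94.0]). A further gene, kremen1, was 33.0-fold higher (15-fold with doublet calls kept in), at 131 CPM against 738 CPM in the CSF-contacting neuron-like cluster 14. These 3 were above both gauges, and fosl2 (38.9-fold; 82.8-fold with free RNA subtracted at 5% and 25.6-fold after thinning) was not. kcnt2 was 9.65-fold lower (a ratio of 0.0661 after thinning) and the chromatin protein gene hmga2 4.09-fold. In the same cells the complement gene c6 was at 910 CPM against 83.2 (10.9-fold [9.45 to 12.7]), with 43.3 CPM in lymphocyte-like cells.

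Oligodendrocyte-like cells had crlf1a at 669 CPM against 3.10 (216-fold [142 to 345]; 134-fold for the mean of per-cell CPM) and the integrin gene itgb6 at 136 CPM against 1.55 (88.0-fold [49.0 to 177]), both above the gauges (itgb6 50.4-fold with the haemoglobin estimate). The neurotrophic factor gene ndnf (326-fold [158 to 812]; 790-fold after thinning) and adam8a (70.5-fold) were not. All 4 were highest in the Schwann cell-like cluster at day 7, where ndnf was at 1364, itgb6 at 1201 and crlf1a at 1847 CPM. The giant muscle protein gene ttn.1 (12.2-fold), dicp1.1 (9.75-fold) and tuft1a (9.73-fold; not above both gauges) were lower. In ependymo-radial glia-like cells clcf1 (117-fold [32.2 to 967]; 49.0-fold after thinning), adam8a (54.7-fold), mmp9 and the annexin gene anxa2a (24.8-fold) were highest, and none was above both gauges. lin28a there was 378-fold higher [67.8 to 14964] than its 1 control UMI (95.9-fold after thinning), with 13.8 CPM in lymphocyte-like cells and none detected in erythrocyte-like cells. The amino acid transporter gene slc38a3b (8.20-fold), ppp1r1b (7.55-fold) and efemp2b (6.29-fold) were lower. All 3 were highest in control in cluster 25 (742, 475 and 662 CPM), and with the mean of per-cell CPM the ratio was 0.186 for slc38a3b and 0.299 for efemp2b. In neuron-like cells adam8b (20.9-fold), ifi45, the tubulin gene tuba1b (10-fold) and the apolipoprotein gene apoc1 (9.47-fold) were highest, none above both gauges; arvcfa (2.59-fold), rxfp2b (2.58-fold) and epb41l4b (2.41-fold) were lower, with ratios of 0.686, 0.65 and 0.689 under the haemoglobin estimate.

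At day 7, differences shared by all classes were also found in lymphocyte-like cells, so free RNA is open for them. Median-of-ratios scaling would lower all log2 ratios of oligodendrocyte-like cells by 0.11 for day 1 against control and raise them by 0.12 for day 7 against day 1, and would move those of the other 3 classes by 0.10 or less. With members at 0 in 1 library set to the floor, the interferon response median of ependymo-radial glia-like cells at day 7 was 1.38 and that of precursor-like cells at day 1 was 2.28.

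Day 7 was compared with day 1 to ask which differences belong to the early and which to the late response. Early response genes were lower at day 7 in oligodendrocyte-like cells: immediate-early genes had a median log2 ratio of −1.05 [−1.61 to −0.44] (23 of 27 lower), interferon response genes −0.75 [−1.52 to −0.30] (16 of 19 lower) and glial injury genes −0.51 [−1.09 to −0.16] (29 of 36 lower). In neuron-like, ependymo-radial glia-like and precursor-like cells the medians were −0.36, 0.16 and −0.12 for immediate-early, 0.18, 0.91 and −0.26 for interferon response and −0.15, −0.15 and −0.28 for glial injury genes. The interferon response median of ependymo-radial glia-like cells had an interval of −0.15 to 1.44 (14 of 19 higher) and was 0.19 after thinning, and that of neuron-like cells was −0.20 with members of at least 50 UMIs. Cell cycle genes were higher in ependymo-radial glia-like (1.62 [1.19 to 2.06], 27 of 27), neuron-like (1.30), precursor-like (1.06) and oligodendrocyte-like cells (0.96). In complement, 2 genes were lower: c4b was 15.6-fold lower [13.6 to 17.9] in ependymo-radial glia-like cells (562 CPM at day 1 and 36 at day 7) and c7b 7.67-fold lower, though c7b was at 2223 CPM in lymphocyte-like cells at day 1. In precursor-like cells lin28a was at 134 CPM at day 7 against 598 at day 1.

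In precursor-like cells pdgfrb, a growth factor receptor gene of mural cells and fibroblasts, was 12.6-fold lower [10.1 to 15.8] at day 7 (711 CPM at day 1) and the receptor gene gfra1a 9.54-fold lower. At day 1 pdgfrb was highest in cluster 11 (1519 CPM). gfra1a was highest in the neuron-like cluster 17 (3517 CPM, against 501 CPM in precursor-like cells). With doublet calls kept in the ratios of day 7 to day 1 were 0.182 for pdgfrb and 0.283 for gfra1a, and gfra1a had 0.0562 with free RNA subtracted at 5%. The mitochondrial ketone enzyme gene oxct1b was 5.15-fold and prxl2b 6.16-fold higher. In oligodendrocyte-like cells tuft1a was 12.5-fold and the transcription factor gene cebpd 15-fold lower, and the apolipoprotein gene apoeb was 12.8-fold and the chemokine gene ccl34b.1 16.8-fold higher, both below the erythrocyte-like level. cebpd (which was without cluster 31), prxl2b and these were not above both gauges, nor were the remaining named genes other than c4b: ccl34b.1 (18.6-fold) and lgals2a (17.3-fold; 11.48-fold for the mean of per-cell CPM) were higher in ependymo-radial glia-like cells, col1a2 (20.8-fold) and apoc1 (13.1-fold) were higher in neuron-like cells, and timp2b (4.69-fold) and cbx7a (3.96-fold) were lower there. Notch pathway genes were higher at day 7 than at day 1 in ependymo-radial glia-like cells for 17 of 22 members (median 0.36 [0.11 to 0.76]). Cluster 15 of this class has the list members dla, dlb and notch1b among its leading genes. It held 200 cells at day 1 and 479 at day 7, so a different mix of clusters cannot be told apart from a change within cells.

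The microglia-like cells of cluster 13 numbered 178 in control and 868 at day 7, and were compared because this cluster held most of the class at day 7. At day 7 these cells had higher levels of gab2, a signalling adaptor gene, at 661 CPM against 5.96 from 1 UMI (111-fold [19.8 to 4384]; 35.6-fold with free RNA subtracted at 5%, 21.1-fold with the haemoglobin estimate and 37.4-fold after thinning) and of fap, a protease gene, at 412 CPM (69.1-fold [12.3 to 2735]; 23.0-fold with free RNA subtracted at 5%). pawr was 21.1-fold higher [8.98 to 65.0] (12.6-fold after thinning and 32-fold for the mean of per-cell CPM) and g0s2, an inhibitor of fat breakdown, at least 20.2-fold. All 4 were above both gauges, but gab2 was higher in the B lymphocyte-like (1334 CPM) and Schwann cell-like (1044 CPM) clusters and pawr in endothelial-like cells (800 CPM against 627). Lower genes were the cytokine gene il1b (4.63-fold [3.67 to 5.84]; a ratio of 0.330 after thinning), the class II antigen presentation gene mhc2dab (3.80-fold [2.97 to 4.83]) and csf1rb (2.77-fold [2.42 to 3.17]), one of the markers that named the cluster. Lysosome and phagocytosis genes were higher for 21 of 25 members (median 0.56), with apoeb 5.76-fold higher [4.79 to 6.99] at 3984 CPM, against 3406 in erythrocyte-like cells. Antigen presentation genes had a median of −0.36 (12 of 18 lower), and the list of infiltrating macrophage genes 1.04 (8 of 12 higher), or 0.57 with members at 0 set to the floor. The median of the latter list was larger in lymphocyte-like cells at day 7. Its member with the largest ratio, anxa2a, was at 230 CPM, against 254 CPM in lymphocyte-like and 383 CPM in erythrocyte-like cells. The list of microglia genes had a median of 0.23. The control sum was 167771 UMIs, and 9 of the 24 measured cell cycle genes were at 0 in 1 library, so that their median of 1.36 became 0.22 with these at the floor.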

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

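No test was run on the shares in this part; leaving out cluster 1 was chosen after the data had been seen, while keeping doublet calls and centring were fixed before. The share of microglia or macrophage-like cells stands out because the 2 times after injury lie on opposite sides of control (3.22%): 1.19% at day 1 and 6.95% at day 7. The share of neuron-like cells stands out in the same way, above control (23.6%) at day 1, at 28.2%, and below it at day 7, at 11.6%. Each is 1 library per group, and the difference between the times was not tested. Shares are parts of a whole, so a large share of another class lowers every other share, and without cluster 1 the day 7 values were 9.38% and 15.6%, on the same sides of control.

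The microglia value at day 1 also depends on the clustering: with doublet calls kept in it was 6.58% against 3.72% in control, and with expression centred within each library 7.07% against 5.36%. The unnamed cluster 20 has il1b, csf1ra and spi1b among its leading genes, but its highest marker score was for neutrophils (3.825, against 2.746 for microglia or macrophages). Cells like those of this cluster joined the microglia or macrophage-like class in both of these clusterings.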

How the results depend on the processing

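The other leading-gene checks, shares without cluster 1, free RNA at 5%, cycling shares without cluster 15 and gauges without cluster 31 were tests chosen after seeing the data; the other alternatives were fixed before the data were examined. Shares are in % of kept cells, and the cause of a difference was not tested unless a reason is given.

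With the stricter cell filter, which removes shallow cells, 30 of 36 shares moved beyond their intervals. Control: B lymphocyte-like 0.582, T or NK lymphocyte-like 3.41, erythrocyte-like 0.334, fibroblast-like 0.322, microglia or macrophage-like 1.37, neuron-like 25.6, oligodendrocyte-like 39.0, precursor-like 11.8. Day 1: B lymphocyte-like 0.372, CSF-contacting neuron-like 6.51, T or NK lymphocyte-like 1.43, endothelial-like 1.22, ependymo-radial glia-like 14.0, erythrocyte-like 0.825, fibroblast-like 0.488, microglia or macrophage-like 0.709, neuron-like 32.2, oligodendrocyte-like 26.1, precursor-like 13.1. Day 7: B lymphocyte-like 0.749, CSF-contacting neuron-like 3.44, Schwann cell-like 5.87, T or NK lymphocyte-like 2.23, endothelial-like 1.96, ependymo-radial glia-like 19.7, erythrocyte-like 0.25, microglia or macrophage-like 5.79, neuron-like 15, oligodendrocyte-like 27.7, precursor-like 6.25.

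With doublet calls kept in, 17 of 36 moved. Control: CSF-contacting neuron-like 4.95, T or NK lymphocyte-like 7.82, ependymo-radial glia-like 10.2, microglia or macrophage-like 3.72, neuron-like 21.9, precursor-like 9.82. Day 1: CSF-contacting neuron-like 5.85, T or NK lymphocyte-like 4.72, ependymo-radial glia-like 12.6, microglia or macrophage-like 6.58, neuron-like 26.8. Day 7: B lymphocyte-like 0.597, CSF-contacting neuron-like 2.78, Schwann cell-like 4.60, T or NK lymphocyte-like 5.06, microglia or macrophage-like 31.3, precursor-like 4.90.

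With each library clustered alone, 15 moved. Control: CSF-contacting neuron-like 8.41, ependymo-radial glia-like 10.3, neuron-like 21.2, oligodendrocyte-like 31.5. Day 1: CSF-contacting neuron-like 4.51, Schwann cell-like 0, endothelial-like 1.74, ependymo-radial glia-like 12.3, fibroblast-like 0, neuron-like 27.4. Day 7: B lymphocyte-like 1.55, fibroblast-like 0.742, microglia or macrophage-like 6.29, neuron-like 13, oligodendrocyte-like 18.2.

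Without cluster 1, which takes cells out of the denominator, 12 day 7 shares moved: B lymphocyte-like 1.28, CSF-contacting neuron-like 3.32, Schwann cell-like 5.41, T or NK lymphocyte-like 5.30, endothelial-like 2.09, ependymo-radial glia-like 20.8, erythrocyte-like 2.40, fibroblast-like 1.42, microglia or macrophage-like 9.38, neuron-like 15.6, oligodendrocyte-like 26.8, precursor-like 6.03.

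With expression centred within each library, 8 moved: in control CSF-contacting neuron-like 4.02, microglia or macrophage-like 5.36, oligodendrocyte-like 36; at day 1 CSF-contacting neuron-like 4.78, microglia or macrophage-like 7.07, oligodendrocyte-like 27.1; at day 7 microglia or macrophage-like 31.1, neuron-like 13. At Leiden resolution 2.0, 7 moved: in control CSF-contacting neuron-like 3.81, neuron-like 25.4; at day 1 CSF-contacting neuron-like 4.75, ependymo-radial glia-like 13.9, precursor-like 7.44; at day 7 ependymo-radial glia-like 40.6, neuron-like 12.3. With leading genes taken against all other cells pooled, and in at least 5% or 25% of cells, clusters 2 and 17 lost their names. Both gave neuron-like 21.7, 25.8 and 10.7 in the 3 libraries and oligodendrocyte-like 3.30 at day 1. At 5% cluster 26 lost its name too, with CSF-contacting neuron-like 3.70 in control and 4.54 at day 1. The other 2 versions moved 0 of 36. In 3 of the 5 versions, both pooled ones and the median with 5% of cells, cluster 20 took the name neutrophil (3.81% of day 1 cells), a class not among the 36.

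Of 18 differences from control whose intervals do not overlap, the direction turned for 1 in each of 4 settings: microglia or macrophage-like cells at day 1 with doublet calls kept in and with centring, erythrocyte-like cells at day 7 with the stricter filter (0.25 against 0.334), and fibroblast-like cells at day 1 with libraries clustered alone (0 against 0.488). It turned for 0 under the other 6.

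Every cycling share moved with the definition. With at least 3 cell cycle genes, which asks for more, it was 0.0317, 0.133 and 0.409 in oligodendrocyte-like, 0.0484, 0.0361 and 0.601 in neuron-like, 5.65, 4.05 and 10.7 in ependymo-radial glia-like and 1.67, 1.87 and 6.53 in precursor-like cells. After thinning to 2000 UMIs, which leaves more UMIs, it was 3.54, 2.91 and 10.8, then 1.74, 2.11 and 9.56, then 12.1, 10.1 and 32.1, then 7.69, 10.9 and 21.2 in the same order. Without cluster 15 the ependymo-radial glia-like shares were 3.27, 2.96 and 12.6, as this cluster holds most of the cycling cells.

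Of 240 list medians, 240 stayed within their intervals with centring and with members of at least 50 UMIs. These intervals are ranges over the members of a list, so the median of a part of the members can hardly leave them. Staying within them does not mean a small move, and the large moves given above, as for cytokines in neuron-like cells at day 1, count as within. With median-of-ratios scaling 2 moved: synapse genes in oligodendrocyte-like cells at day 1 to −0.25 and oxidative phosphorylation in ependymo-radial glia-like cells at day 1 to 0.33. After thinning 4 moved, all for day 7 against day 1: oxidative phosphorylation in oligodendrocyte-like (0.50) and neuron-like (0.78), Wnt pathway in neuron-like (0.49) and cell cycle in ependymo-radial glia-like cells (1.13). Lists in lymphocyte-like cells and cluster 13 were not recomputed.

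Of the named gene ratios, the haemoglobin estimate moved 85 of 134 and turned 8: in oligodendrocyte-like cells at day 1 rsad2 0.745, cd74a 10.8 and sox10 0.924; in neuron-like cells loxl3b 6.81 at day 1 and galn 1.05 and syn2b 1.001 at day 7; lama4 0.2005 in precursor-like and pyya 1.93 in lymphocyte-like cells at day 7. That estimate takes most UMIs of each library for free RNA, so its values are extreme. It rests on no measured profile of free RNA and cannot say how much free RNA the cells hold. Thinning to 1000 UMIs moved 27 of 157 and turned 2: slc17a6b 0.933 in neuron-like and hmgcra 0.852 in ependymo-radial glia-like cells at day 7. The mean of per-cell CPM moved 28 of 159, keeping doublet calls 13 of 149, the stricter filter 5 of 149, free RNA at 5% 3 of 162 and median-of-ratios scaling 2 of 159, and none of these turned a ratio. Where a class or gene had no value under an alternative, none is counted.

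Erythrocyte-like cells without cluster 31, whose second score is for oligodendrocytes, put 2 named genes above both free RNA gauges that had not been: gbp1 in oligodendrocyte-like cells at day 1 (291 CPM, against 301 CPM in all erythrocyte-like cells and 108 CPM without cluster 31) and cebpd there (373, 239 and 159 CPM). The other named genes stayed on their side.

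No paired analysis was possible because each group is 1 library and the labels name no shared animal. Depth limits the cycling shares: cells under 1000 UMIs, 328 of 524 lymphocyte-like cells at day 7, were left out.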

Other observations

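Iron and haem genes were highest against control in oligodendrocyte-like cells at day 1, and lysosome genes were higher in the 4 classes at both times. The tests of deeper cells, library difference, evenly added free RNA, the Schwann cell-like cluster and low depth were chosen after the result had been seen, and the tests of free RNA in ependymo-radial glia-like cells, neuron-like cells and cluster 1 before. Iron and haem genes, which handle iron from broken-down blood, had median log2 ratios of 0.83, 0.12, −0.03 and 0.40 at day 1 and 0.38, 0.20, 0.06 and 0.71 at day 7 in oligodendrocyte-like, neuron-like, ependymo-radial glia-like and oligodendrocyte precursor-like cells, and 0.75 and −0.02 in lymphocyte-like cells. Lysosome and phagocytosis genes had 0.22, 0.37, 0.20 and 0.31 at day 1 and 0.74, 0.67, 0.64 and 0.60 at day 7, and 0.27 and 0.32 in lymphocyte-like cells. Glycolysis genes had 0.51, 0.06, 0.35 and 0.32, then 0.31, 0.13, 0.40 and 0.19, with 0.37 and 0.34 in lymphocyte-like cells.

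Wnt pathway genes had medians of 0.50, −0.03, −0.25 and −0.14 at day 1 and −0.08, −0.12, −0.30 and −0.08 at day 7 in the same 4 classes. The Wnt medians of neuron-like cells at both times, the iron medians of ependymo-radial glia-like cells at both times and that of neuron-like cells at day 1 had the other sign under at least 1 alternative. Genes of infiltrating macrophages had 1.86, 1.82, 1.03 and 2.55 at day 1 and 1.83, 0.55, 1.64 and 1.22 at day 7, and genes of microglia had 0.83, 0.39, 0.43 and 0.60, then 1.82, 1.45, 1.51 and 1.48. With only members of at least 50 UMIs the infiltrating macrophage medians at day 7 were 2.89 in neuron-like and 2.49 in ependymo-radial glia-like cells, and after thinning 1.34 in neuron-like cells. At day 1 they were 1.21 in oligodendrocyte-like and 1.11 in neuron-like cells with at least 50 UMIs, and 1.16 in neuron-like and 3.17 in precursor-like cells after thinning. The microglia medians were 1.13 in oligodendrocyte-like cells at day 7 with at least 50 UMIs and −0.02 in neuron-like cells at day 1 after thinning. These lists belong to other cells, and lymphocyte-like cells had 2.02 and 2.47 for infiltrating macrophage genes and 0.27 and 1.38 for microglia genes. Complement genes had 2.09, 1.0, 0.51 and 1.47 at day 7, against 1.62 in lymphocyte-like cells.

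Cell cycle genes were higher at day 7 in every class measured, and with 1 library per group a difference between the 2 libraries that does not come from the injury stays open, as does injury itself. Free RNA as the only source in ependymo-radial glia-like cells would give 23.2 day 7 cells with at least 4 cell cycle genes, and 119 [98.6 to 142] had them, which argues against it, but control had such an excess too (27 against 0.716). Free RNA added evenly to control cells until each gene reached its day 7 share of cells would give 77.3 [62 to 96.8], only narrowly fewer than found, and uneven free RNA as the source of the difference from control was not tested and stays open. Deeper cells at day 7 are argued against, since at 1000 UMIs per cell the cycling share was 21.4% [19.5 to 23.4] against 8.07% [6.35 to 10.1] in control. In neuron-like cells 1 such cell was found with 0.324 expected, so free RNA as the only source of their day 7 cell cycle UMIs may account for them.

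The Schwann cell-like cluster came almost wholly from the day 7 library. Doublets or free RNA from other clusters would give a mix of their profiles. Yet 15 genes with at least 100 UMIs had over 5 times the CPM of the highest other day 7 cluster compared. Among them were itih1, scn4ab, cnr1, artnb and the neural crest gene foxd3. Clusters with 46 or fewer day 7 cells were left out of this comparison, so they were not examined as a source. More nerve root or connective tissue in the day 7 dissection cannot be told apart from a response to injury with 1 library per group. A biological explanation was not tested.

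Unnamed cluster 1 held 25.9% of day 7 cells, at a median of 765 UMIs. Of cells with 500 to 1000 UMIs, 57.5% fell in cluster 1 at day 7, against 0.788% in control and 2.08% at day 1. Shallow cells of the other libraries thus mostly fell in other clusters. This cannot decide on low depth, since cluster 1 held 32 control and 103 day 1 cells, which fixed the low shares beforehand. The clusters were also made without batch correction, so low depth stays open. Droplets that hold only free RNA met neither prediction: the variance over the mean was to be under 1.1 in all of 14 marker lists and was above it in 12, and 5 lists were above 1.2 at the lower bound, where at least 7 were needed against this explanation. In lymphocyte-like cells, where these markers should be free RNA, the oligodendrocyte list had 1.74 against 1.70 in cluster 1, but the neuron list had 1.103 against 1.58 and the ependymo-radial glia list 1.18 against 1.56, so this comparison goes both ways and free RNA stays open. A first test of it, by closeness to the average of the library, was judged void after it had been run and was replaced by this one; what these cells are stays open, and no biological explanation was tested.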
